A study of Mus musculus with 12 samples.

How the data were processed

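Total RNA and ribosome footprints were measured in mouse embryonic fibroblasts (MEF), connective tissue cells grown from mouse embryos. Cells were kept for 6 h in medium with dialyzed serum, which lacks most free amino acids of serum, with or without 100 nM halofuginone (HF), a compound known to block the prolyl-tRNA synthetase activity of EPRS. Per the labels, the 12 libraries form 4 groups of 3: total RNA of control cells, total RNA of HF cells, footprints (RPF, ribosome-protected fragments) of control cells and footprints of HF cells. Groups and replicate numbers were taken from the library titles. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

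Per the labels' protocols, RNA was extracted with Trizol, total RNA was broken by alkaline hydrolysis, and footprints were made by RNase I digestion and collected from the monosome fraction of a sucrose gradient. Both kinds of fragment were selected by size on a gel, and depletion of ribosomal RNA is described for the footprint libraries. Bowtie, HISAT2, HTSeq and the build GRCm38 are named, per the submitters' processing notes, without versions or order. The authors deposited a table of whole-number counts of reads per gene for each library, with no normalization. The counted feature (whole transcript or coding region), the use of strand and the treatment of reads that map to several places are not given in the sources used here. Footprints on upstream reading frames may therefore be part of a gene's count, genes that overlap or lie antisense to each other cannot be told apart, and genes with near-identical copies (ribosomal proteins, histones, Gapdh, Ftl1) are uncertain. No genome sequence was used here.

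Each table lists 55536 gene IDs, of which 55450 had a symbol in the ID table and 38663 a gene type in the RefSeq table, 21421 of them protein-coding. There were 0 entries that name no gene, and 0 columns that belong to no sample. Coordinates are those of the RefSeq annotation of GRCm38, counted from 1, and give the whole gene including introns. Low counts were mostly even. In RNA control 1, for example, 1541 genes had 2 counts and 419 had 1, while 820 had 4 and 138 had 3. The sources used here do not say why.

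Library totals ran from 562794 to 2527791 counts. The tests were run in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr with its minimum count of 10) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Total RNA was tested over all genes and footprints over protein-coding genes, each on its own 6 libraries. Translational efficiency (TE), footprints relative to total RNA, was tested as the interaction of assay and treatment in a single model over the 12 libraries, with TMM factors within each assay and genes that passed the filter in both. A standard error (SE) was obtained from the fold change and its F statistic. CPM values (counts scaled to a common library total) were scaled by TMM factors computed here from the deposited counts. Fold changes beside CPM values are those of the fit and can differ from the ratio of the means. All changes are relative to the bulk of genes, since no spike-in is described, and a shift of all genes together would not be seen.

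Gene lists fixed in advance were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, for lists with at least 5 tested genes. Calls were also computed with the correlation estimated for each list. That setting also rests on the residual degrees of freedom of the fit, 4 in RNA and in footprints and 8 in TE. A call can therefore be lost there without a higher correlation. Its adjusted p-values are given where a call is lost, and for some lists where it was kept. Counts "adjusted over the list alone" use the Benjamini-Hochberg adjustment within the list. The lists cover the integrated stress response (ISR), mRNAs with regulatory upstream open reading frames (uORF), tRNA synthetases, amino acid transport and synthesis, ribosomal proteins and other mRNAs with a 5' terminal oligopyrimidine tract (TOP), ribosome biogenesis, mitochondria, matrix, TGF-beta targets, the cell cycle, histones, other stress pathways, autophagy, metabolism, p53 targets, early and inflammatory genes, eIF2 and mTORC1 signalling, and markers of fibroblasts and of other cell types. The list of TGF-beta targets also holds targets of YAP signalling. Some lists share members, so their calls are not independent. Atf4, Atf5, Ddit3, Ppp1r15a and Cebpb, for example, are in both the ISR and the uORF list.

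Named genes were set by a rule. In each comparison the rule took the 8 highest and 8 lowest fold changes among protein-coding genes that passed the test with a mean log2 CPM of at least 3, without overlap between groups for RNA and footprints. It also took 16 genes named beforehand, and up to 4 members of each list with the largest change among those that passed. The 16 genes are given whatever their result, except that TE values of Ibtk, Eif2ak4, Aldh18a1 and Pycr1 are not printed. List members whose call ended when 1 library was left out are mostly not printed, and where printed, that is said. Where none of a list passed, values of its best-expressed members were allowed. Lists, rule, designs and the alternatives in the frozen plan were chosen before the data were examined.

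Because low counts came mostly in even numbers, the floor was set to 6 counts over a group, the equivalent of 3 reads counted in pairs. A gene at 0 in a group is given as at least a stated fold, against that floor. With 1 to 6 counts in a group, the ratio of scaled counts is given with a 95% interval, exact (Clopper-Pearson, on halved counts) for RNA and footprints and from 10000 simulated draws for TE. These intervals and floors cover counting error only. Chi-square statistics between replicates ran from 2.26 to 4.45 per gene, and the lower values are near what sampling alone would give were reads counted in pairs. Each library was counted once.

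On simulated counts drawn from the real means and library sizes, the RNA step (8837 genes) recovered 25.4% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 92.4% of those changed 4-fold, and 4.88% of its calls were false. The footprint step (8201 genes) recovered 25.4%, 59.7% and 93.9%, with 4.03% false. For TE (7715 genes) the shares were 10.4%, 43.3% and 87.9%, with 2.08% false, so most simulated TE changes of 1.5-fold or 2-fold were missed. In each step only 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. Many more genes were called in the real data, which moves the adjusted threshold, so these shares need not hold there.

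Alternatives included DESeq2 1.42.0, limma voom, other scaling factors, no filter or a minimum count of 50, all genes or coding genes only, the replicate number as a block, and leaving out each library. Chosen after seeing the data were thinning of all libraries to the smallest total (562794 counts), halving of the counts, and leaving out both footprint libraries that stood apart. A planned comparison of codon content with TE was not run, because coding sequences were not analysed here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.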

Results

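Mouse embryonic fibroblasts (MEF) were grown for 6 h with 100 nM halofuginone (HF) or without it, in medium with dialyzed serum, and each culture condition was read by total RNA sequencing and by ribosome footprints (RPF). Each of the 4 groups had 3 libraries. Total RNA libraries held 718096 to 1295434 counts in control cells and 1017651 to 1697554 in HF cells. Footprint libraries held 724609 to 2527791 counts in control cells and 562794 to 1958356 in HF cells. Nuclear protein-coding genes took 96.0% of the footprint counts of control cells and 96.4% of those of HF cells. In total RNA they took 75.4% ± 1.31 (SD, n = 3) in control and 81.0% ± 1.13 in HF libraries, while Gm42418, a locus that overlaps ribosomal RNA, went from 12.7% ± 0.952 to 8.31% ± 1.08. Among footprints this locus stood out in RPF control 1, at 1.12% against 0.0933% and 0.0977% in the other control libraries. In a principal component analysis of each assay, the first component separated HF from control libraries and held 85.2% of the variance in RNA and 85.6% in footprints, while RPF HF 3, the library with the fewest counts, lay apart on the second footprint component, which held 5.77%. RNA control 2, the RNA library with the fewest counts, lay at −10.7 on the second RNA component (4.93%), against 4.35 and 6.19 for the other controls.

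The RNA comparison asks which transcripts differ after 6 h with an inhibitor of prolyl-tRNA charging, in a series about the amino acid sensor GCN2 and mTORC1. Transcripts of the integrated stress response rose together. Ddit3, which encodes the transcription factor CHOP, went from 5.96 ± 1.95 CPM (SD, n = 3) to 63.2 ± 4.96, and Trib3, a pseudokinase target of ATF4 and CHOP, from 10.5 ± 0.807 to 119 ± 30.9. Atf4 itself rose by 1.37-fold, from 612 ± 45.0 to 840 ± 37.2 CPM. Transcripts of sterol synthesis fell, as did most ribosomal protein transcripts, while histone, DNA replication and early-response transcripts rose.

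Of 9145 genes tested in total RNA, 3992 changed, with 2031 higher and 1961 lower in HF cells. At least 2-fold changes were called for 1081 higher and 888 lower genes. HF and control libraries did not overlap in 4695 genes, of which 3714 were called, where chance gives 10%. In the integrated stress response list, 11 of 14 tested genes rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 9.9e-08). Log2 fold changes were 3.34 for Ddit3 (ENSMUSG00000025408, chromosome 10 from 127290793 to 127296291; SE 0.37, edgeR adjusted p = 7.0e-12), 3.49 for Trib3 (SE 0.28), 4.32 for Atf3 and 3.12 for Chac1, a glutathione-degrading enzyme. Ddit4, an inhibitor of mTORC1 signalling, fell by 1.62. Among mRNAs known for regulatory upstream open reading frames, 10 of 11 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.7e-08), including Ppp1r15a (the eIF2 phosphatase subunit GADD34; 2.66, SE 0.20), Ifrd1 (2.00) and Cebpb (1.53). Further ATF4-linked genes named in advance also rose. Atf5 changed by 1.49 (SE 0.20), the stress sensor Sesn2 by 2.55 (SE 0.28), asparagine synthetase Asns by 1.00 (SE 0.11) and the proline synthesis enzyme Aldh18a1 by 1.00 (SE 0.12). The cystine transporter Slc7a11 went from 2 to 72 counts, a 27.1-fold difference with a counting interval of 4.57 to 1101, with the 2 control counts all in RNA control 1. Ibtk passed at 0.78 (SE 0.26, edgeR adjusted p = 0.012), and the call ended without RNA control 1 (0.44, adjusted p = 0.21) or RNA HF 2 (0.68, adjusted p = 0.069), while the value was 1.18 without RNA control 3. Eif2ak4, which encodes GCN2, at −0.47 (adjusted p = 0.20), and Pycr1, a proline synthesis enzyme, at −0.02 (adjusted p = 0.98), did not pass.

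Transcripts of cytosolic tRNA synthetases rose as a group. Of the 20 cytosolic tRNA synthetases, 10 rose, 2 fell and 8 did not pass (11 and 2 adjusted over the list alone; camera adjusted p = 4.9e-05). Eprs, the glutamyl-prolyl-tRNA synthetase that HF inhibits (ENSMUSG00000026615, chromosome 1 from 185361417 to 185428360), was 2.47-fold higher, and Rars (1.33), Lars (1.30) and Aars (1.23) were among those that rose. Mitochondrial tRNA synthetases had 3 of 16 higher and 5 lower, among the latter Cars2 (−1.93) and Vars2 (−1.26), and were not called as a list (camera adjusted p = 0.30). Amino acid transporters had 6 of 14 higher and 2 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.069), with Slc7a1 at 1.46, Slc1a4 at 1.24 and Slc3a2 at 0.96. Their list was called without RNA control 1 (adjusted p = 0.029) or RNA HF 2 (adjusted p = 0.039). Enzymes of amino acid synthesis had 8 of 21 higher and 2 lower (camera adjusted p = 0.077), Gpt2, an alanine aminotransferase, at 1.41.

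Ribosomal protein transcripts fell in 52 of 76 cases and rose in 0 (56 lower adjusted over the list alone; median −0.61; camera adjusted p = 2.3e-12). The camera adjusted p was only 0.043 with an estimated correlation. With relative log expression factors 50 fell, and with upper-quartile factors 56. Rpl37a (−1.96) and Rpl11 (−1.77) are examples. Other TOP mRNAs, which encode translation factors, had 10 of 18 lower and 1 higher (11 and 1 adjusted over the list alone; camera adjusted p = 3.5e-05), with Eif3f at −0.95, Eif4b at −0.85 and Eif3a at 0.92. The elongation factors Eef2 and Eef1a1 fell by 0.68 and 0.50. Ribosome biogenesis factors went both ways, 5 higher and 5 lower of 24 (camera adjusted p = 0.77), with Nop58 at 1.11 and Ubtf at −0.92. Nuclear-encoded respiratory chain subunits fell in 15 of 34 cases and rose in 0 (camera adjusted p = 0.0020), with Sdhb at −0.94 and Atp5o at −0.76. Mitochondrial ribosomal proteins had 1 of 32 higher and 7 lower (camera adjusted p = 0.087), Mrps15 at −1.01. Of the 11 mitochondrially encoded mRNAs 7 fell (camera adjusted p = 3.2e-05; adjusted p = 0.14 with an estimated correlation), with mt-Nd5 at −0.90 and mt-Nd1 at −0.76.

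Sterol and fatty acid synthesis transcripts fell in 19 of 23 cases, and 0 rose (camera adjusted p = 4.0e-11). Nsdhl (−3.02), Hmgcs1 (−2.48) and Dhcr7 (−2.03) encode sterol synthesis enzymes, and the desaturase Scd2 went from 1871 ± 141 to 431 ± 9.98 CPM. Glycolysis and hypoxia genes had 10 of 16 lower and 3 higher (camera adjusted p = 0.011; adjusted p = 0.080 with an estimated correlation), with Pfkm at −2.17, Pfkl at −1.41 and the growth factor Vegfa at 1.77. Autophagy and lysosome genes had 10 of 25 higher and 2 lower (median 0.30; camera adjusted p = 0.0021; adjusted p = 0.071 with an estimated correlation), with the autophagy receptor Sqstm1 at 2.11, Fnip1 at 1.81 and Atp6v0d1 at 1.53. The median was 0.45 without RNA HF 2. Genes of eIF2 and mTORC1 signalling had 7 higher and 6 lower of 26 (8 and 6 adjusted over the list alone; camera adjusted p = 0.81), with Eif4ebp2 at −1.91 and the autophagy kinase Ulk1 at −1.34.

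Replication-dependent histone transcripts rose in 59 of 60 cases (median 1.64; camera adjusted p = 1.7e-45), among them Hist1h2bp at 3.30, and DNA replication genes in 21 of 26 with 0 lower (median 0.80; camera adjusted p = 8.4e-08), among them Cdt1 (1.83) and Cdc6 (1.74), which load the replicative helicase, and Mcm4 (1.61), a part of it. The histone list had a camera adjusted p of only 0.023 with an estimated correlation. Mitosis genes had 5 higher and 5 lower of 24 (median −0.10, mean 0.07; camera adjusted p = 0.84). Immediate early genes rose in 15 of 17 cases and fell in 1 (camera adjusted p = 5.7e-14). Egr1, an early-response transcription factor (ENSMUSG00000038418, chromosome 18 from 34861207 to 34864956), rose 82.3-fold from 25.2 ± 4.30 to 2053 ± 87.0 CPM, and Ier2 by 3.17. Of p53 targets 6 of 13 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.0498; adjusted p = 0.14 with an estimated correlation), with Gadd45a at 4.17, Btg2 at 3.62 and the cell cycle inhibitor Cdkn1a at 2.54. That call ended without RNA control 1 (adjusted p = 0.10), and the list's median went from 0.83 to 0.35 without RNA control 3. In the inflammatory list 2 of 4 tested genes rose, Cxcl10 (3.44) and Tnfaip3 (3.31), too few for a list test.

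Collagen transcripts had 4 of 14 higher and 4 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.30). Col12a1 was at 1.41, and Col1a1 went from 1587 ± 23.8 to 830 ± 31.1 CPM (−0.93, SE 0.08, edgeR adjusted p = 6.2e-15). Other matrix genes had 4 of 19 higher and 9 lower (5 and 9 adjusted over the list alone; camera adjusted p = 0.51), with fibronectin Fn1 rising from 1540 ± 14.5 to 4979 ± 137 CPM, tenascin Tnc at 2.11, thrombospondin Thbs1 at 1.89 and the prolyl hydroxylase subunit P4ha2 at −2.48. Of TGF-beta targets 9 of 14 rose and 2 fell (camera adjusted p = 1.1e-04; adjusted p = 0.071 with an estimated correlation), with Skil at 1.79, Ankrd1 at 1.57 and Tgfb1 at −1.35. Heat shock genes had 7 of 12 lower and 2 higher (camera adjusted p = 0.0022; adjusted p = 0.062 with an estimated correlation), with the chaperones Hspa8 at −2.51 and Hsph1 at −1.53. Targets of the endoplasmic reticulum unfolded protein response had 4 of 18 higher and 8 lower (camera adjusted p = 0.40), with Herpud1 at 2.10, Xbp1 at 1.02 and Pdia4 at −0.86. Targets of NRF2 had 2 of 10 higher and 3 lower (camera adjusted p = 0.30), with G6pdx at −1.51, Prdx1 at −1.32 and Srxn1 at 1.29. Fibroblast markers had 4 of 9 lower and 0 higher (5 lower adjusted over the list alone; camera adjusted p = 5.3e-04), with the receptor Pdgfrb at −2.30 and S100a4 at −1.23.

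Among the largest RNA changes, several were in transcripts that were rare in 1 group. Pmaip1, which encodes the proapoptotic protein NOXA, went from 0 to 164 counts, at least 20.6-fold higher, and Rassf4 from 0 to 57, at least 7.16-fold higher. Vgf, a neuropeptide precursor, was 256-fold higher (interval 45.7 to 10149), Tcim 104-fold (18.4 to 4137), the ATP-gated channel P2rx7 92.1-fold (25.3 to 767) and Fos 86.7-fold (15.2 to 3452). At the other end, Layn, a hyaluronan receptor, was 18.6-fold lower (4.68 to 161), Atoh8 17.3-fold (4.32 to 150) and Mypop 16.5-fold (4.28 to 70.1). The sulfotransferases Chst1 (−4.25) and Chst12 (−3.92), Eva1b (−3.94) and the anion transporter Slco4a1 (−3.58) had 8, 7, 16 and 8 counts in HF cells. These lie above the floor of 6, so no interval is given, but such low counts leave the values uncertain too. Total RNA values are shares of a pool in which the ribosomal RNA locus took 12.7% in control and 8.31% in HF libraries, and near-identical gene copies such as histones and ribosomal proteins share reads to an unknown degree.

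**Figure D1:**
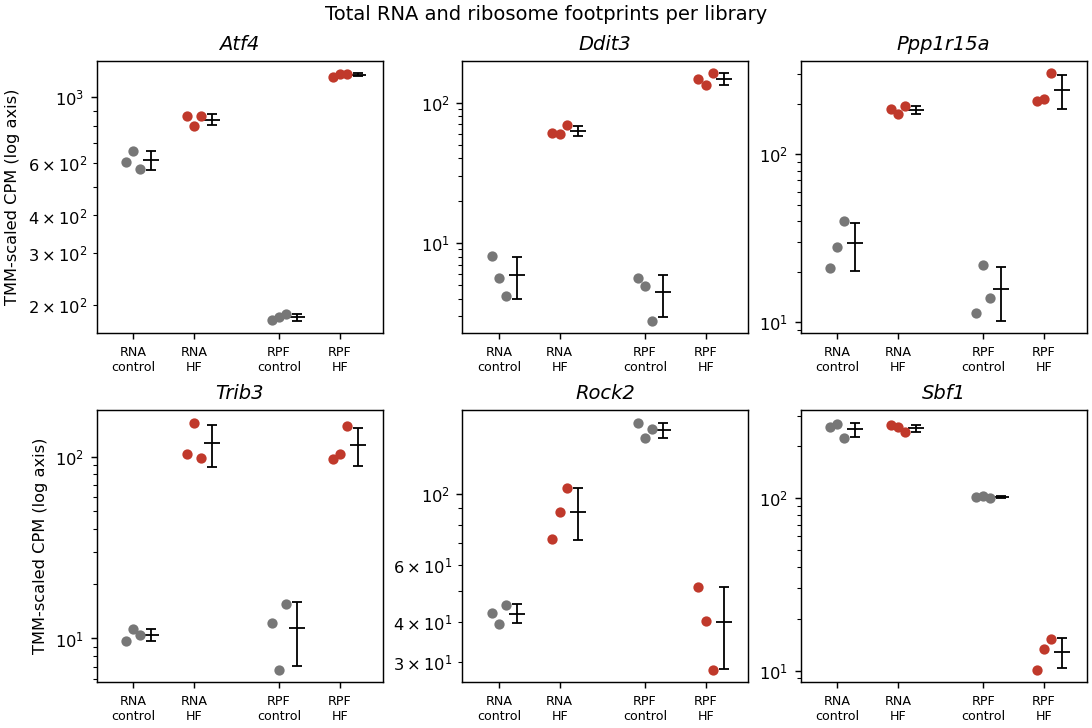
TMM-scaled CPM (log axis) of 6 genes in each of the 12 libraries, with a bar for the mean and SD of each group of 3. Atf4 footprints lie at 182 ± 4.57 in control and 1186 ± 13.9 in HF libraries, while its RNA goes from 612 to 840.

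Footprints report which mRNAs were occupied by ribosomes in the same conditions. Atf4 (ENSMUSG00000042406, chromosome 15 from 80255184 to 80257545), the central transcription factor of this response, rose 6.53-fold, from 182 ± 4.57 to 1186 ± 13.9 CPM (SD, n = 3). Ddit3 footprints rose from 4.46 ± 1.48 to 147 ± 13.6 CPM, a fitted 29.3-fold, and those of Ppp1r15a from 15.8 ± 5.57 to 241 ± 53.9, a fitted 15.1-fold. Histone mRNAs gained footprints as a group, Egr1 rose and the sterol synthesis enzyme Hmgcs1 fell. Rock2, a protein kinase, and Sbf1, a phosphatase-like protein of the myotubularin family, lost footprints without a fall of their RNA.

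Of 8379 protein-coding genes, 3625 changed in footprints, with 1877 higher and 1748 lower, and 989 and 865 at least 2-fold. The libraries of both conditions did not overlap in 4300 genes, of which 3385 were called, where chance gives 10%. In the integrated stress response list 12 of 13 rose and 1 fell (median 2.71; camera adjusted p = 7.5e-11). Log2 fold changes were 2.71 for Atf4 (SE 0.10, edgeR adjusted p = 1.5e-20), 4.87 for Ddit3 (SE 0.28) and 3.92 for Ppp1r15a (SE 0.23). Trib3 (3.38, SE 0.29), Slc7a11 (2.38, SE 0.43), Atf5 (1.56, SE 0.18), Aldh18a1 (1.07, SE 0.11), Eprs (0.71, SE 0.10) and Asns (0.70, SE 0.09) also rose. Sesn2 was at 2.71 (SE 0.44), and at 4.12 without RPF control 2. Of mRNAs with regulatory upstream reading frames 9 of 11 rose and 0 fell (camera adjusted p = 1.2e-08). Ppp1r15b, which encodes the constitutive counterpart of GADD34, did not pass at 0.13. Ibtk passed at 0.72 (SE 0.29, edgeR adjusted p = 0.046), and the call ended without RPF control 1 (0.68, adjusted p = 0.13), RPF control 2 (0.61, adjusted p = 0.16) or RPF HF 1 (0.34, adjusted p = 0.49). Eif2ak4 (0.03, adjusted p = 0.95) and Pycr1 (0.60, adjusted p = 0.23) did not pass.

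Cytosolic tRNA synthetases had 11 of 20 higher and 2 lower (11 and 3 adjusted over the list alone; camera adjusted p = 5.8e-05; adjusted p = 0.067 with an estimated correlation), with Cars at 1.36 and Yars at 1.24. Mitochondrial synthetases had 1 of 16 higher and 4 lower (camera adjusted p = 0.46). Amino acid transporters had 7 of 16 higher and 1 lower (camera adjusted p = 0.16), Slc7a1 at 1.45 and the leucine transporter Slc7a5 at 1.15, and their list was called without RPF HF 1 (adjusted p = 0.045). Amino acid synthesis enzymes had 8 of 21 higher and 5 lower (camera adjusted p = 0.19), with Gpt2 at 1.56 and the pyrroline-5-carboxylate reductase Pycrl at −1.57. Genes of eIF2 and mTORC1 signalling had 5 of 25 higher and 5 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.87).

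Ribosomal proteins went both ways in footprints, 14 higher and 32 lower of 73 (17 and 34 adjusted over the list alone; median −0.31; camera adjusted p = 0.010; adjusted p = 0.067 with an estimated correlation). With relative log expression or upper-quartile factors, 11 to 14 rose and 32 to 34 fell. Rplp1, an acidic protein of the ribosomal stalk, rose from 41.8 ± 11.9 to 145 ± 47.9 CPM, while Rps15 (−1.88), Rps21 (−1.84) and Rps29 (−1.83) fell. Other TOP mRNAs had 10 of 18 lower and 2 higher (camera adjusted p = 0.0017; adjusted p = 0.067 with an estimated correlation), Eef2 falling by 0.50 and Eef1a1 by 0.20. Lists for ribosome biogenesis (5 higher and 4 lower of 24; median 0.06, which changes sign with the scaling; camera adjusted p = 0.66), mitochondrial ribosomal proteins (4 and 4 of 33; adjusted p = 0.89), nuclear-encoded respiratory chain subunits (5 and 10 of 34; adjusted p = 0.20) and mitochondrially encoded mRNAs (0 and 1 of 7; adjusted p = 0.68) were not called. Mrpl12 at 1.46 and Ndufb10 at −1.26 are examples.

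Histone footprints rose on 61 of 63 genes (62 adjusted over the list alone; median 1.61; camera adjusted p = 9.8e-43), with Hist1h2bp at 3.57 and Hist1h2bn at 3.02, and DNA replication genes rose in 18 of 26 cases and fell in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 6.9e-07), with Cdc6 at 1.68 and Rfc4 at 1.67. The histone list had a camera adjusted p of only 0.030 with an estimated correlation. Mitosis genes had 5 of 24 higher and 4 lower (median 0.02, which changes sign with the scaling; camera adjusted p = 0.71). Sterol and fatty acid synthesis fell in 20 of 24 cases and rose in 0 (median −1.13; camera adjusted p = 4.4e-11; adjusted p = 0.067 with an estimated correlation), with Hmgcs1 at −2.56 and Scd2 at −2.03. Glycolysis and hypoxia genes had 9 of 16 lower and 2 higher (10 and 3 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.091 with an estimated correlation), Vegfa at 2.98. Autophagy and lysosome genes had 13 of 25 higher and 2 lower (13 and 3 adjusted over the list alone; camera adjusted p = 0.0034; adjusted p = 0.067 with an estimated correlation), Sqstm1 at 2.82. Immediate early genes rose in 16 of 17 cases (17 adjusted over the list alone; camera adjusted p = 8.6e-15; adjusted p = 0.067 with an estimated correlation), Egr1 by a fitted 155-fold (log2 7.27), with mean CPM of 16.8 ± 9.85 in control and 2215 ± 324 in HF libraries. Targets of p53 had 6 of 13 higher and 2 lower (camera adjusted p = 0.013; adjusted p = 0.094 with an estimated correlation), Gadd45a at 4.96 and Cdkn1a at 3.06. In the inflammatory list 3 of 8 rose and 0 fell (camera adjusted p = 0.15). It was called without RPF control 2 (adjusted p = 0.032), RPF HF 1 (adjusted p = 0.036) or RPF HF 3 (adjusted p = 0.049).

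Collagens had 3 of 15 higher and 5 lower in footprints (camera adjusted p = 0.15). Col1a1 went from 2541 ± 11.2 to 1696 ± 55.2 CPM, Col1a2 fell by 1.23 and Col5a2 rose by 1.06. Other matrix genes had 5 of 19 higher and 9 lower (camera adjusted p = 0.18), with Tnc at 2.71, Fn1 at 0.81, the collagen chaperone Serpinh1 at −1.60 and P4ha2 at −1.92. Of TGF-beta targets 9 of 15 rose and 3 fell (camera adjusted p = 8.1e-04, and 0.12 with an estimated correlation), with Ccn2 at 1.56. The largest change in this list was a fall, with Tgfbi 9.66-fold lower (interval 2.46 to 83.2), from 64 to 4 counts. Heat shock genes had 7 of 12 lower and 1 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.0049; adjusted p = 0.078 with an estimated correlation), Hspa8 at −1.95. Unfolded protein response targets had 5 of 18 higher and 8 lower (camera adjusted p = 0.55) and NRF2 targets 3 of 11 higher and 4 lower (adjusted p = 0.28). Fibroblast markers had 5 of 10 lower and 2 higher (camera adjusted p = 0.0049; adjusted p = 0.078 with an estimated correlation), Pdgfrb at −2.87.

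Among the largest footprint changes, Stmn4, of the stathmin family, went from 0 to 60 counts, at least 16.6-fold higher, and Vgf rose 101-fold (log2 6.66, SE 0.27). Egr2 was 143-fold higher (interval 38.9 to 1186), Fos 110-fold (29.9 to 919), the cytokine Il11 90.0-fold (18.2 to 570) and the activin antagonist Fst 69.2-fold (18.7 to 584). Lower were Slco4a1 by 25.6-fold (6.89 to 215), the receptor Adgra3 by 20.4-fold (5.47 to 173), Gprasp1 by 20.2-fold (3.44 to 834), the cytidine deaminase Apobec3 and Eef2k, the kinase of eEF2, each by 18.0-fold (4.80 to 153), the adenylyl cyclase Adcy7 by 15.2-fold (4.05 to 131) and Shkbp1 by 14.9-fold (3.96 to 128). With RPF control 1 and RPF HF 3, the libraries that stood apart, both left out, 2936 genes were called.

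Across the 7926 genes tested in both assays, RNA and footprint changes were correlated (Pearson r = 0.713, Spearman 0.656). The correlation is across genes, which are not independent replicates, and the RNA and footprint fits share no library. Genes higher in both numbered 1171, where independent lists would share 435, and genes lower in both 956, where 360 would be shared. Opposite calls were made for 78 genes higher in RNA and lower in footprints, such as Rock2, and for 46 the other way, such as Rplp1 and Mrpl12, where 792 opposite calls would come from independent lists.

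**Figure D2:**
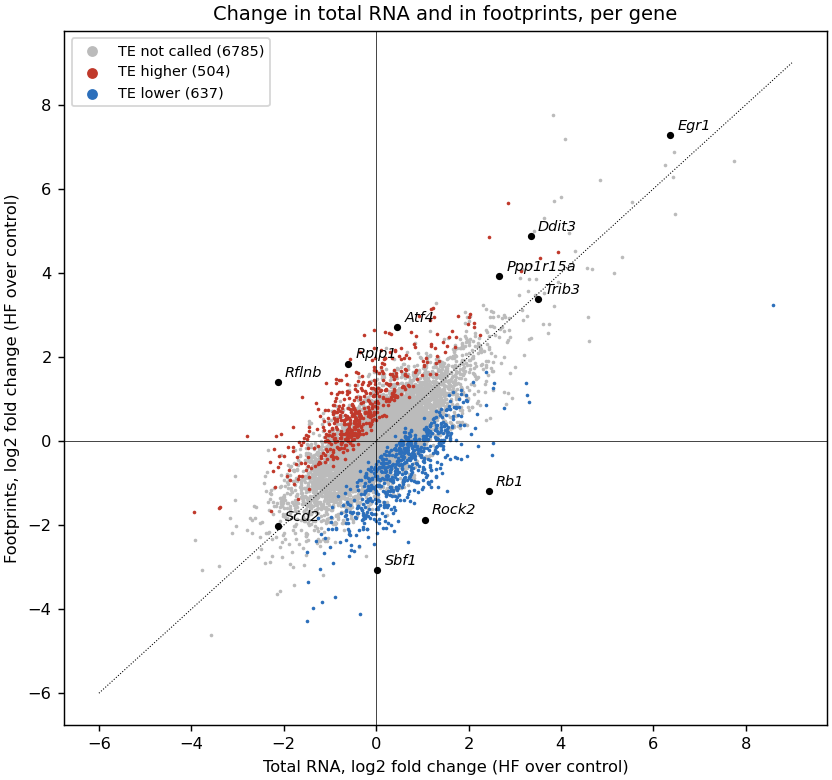
Log2 fold change (HF over control) in footprints against that in RNA for 7926 genes, each point a gene, with a dotted line of equality and fitted values also for genes with few counts. Points above the line include the genes with higher TE, and points below it those with lower TE.

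Translational efficiency (TE), the footprint change beyond the RNA change, asks which mRNAs gained or lost ribosomes for their level. Atf4, with the lowest adjusted p of the 16 genes named in advance, rose 4.81-fold (log2 2.27, SE 0.13, edgeR adjusted p = 2.5e-19). Ribosomal protein mRNAs rose as a group, with a median of −0.61 in RNA and −0.31 in footprints. Sbf1 (ENSMUSG00000036529, chromosome 15 from 89288236 to 89315311) fell by 3.10 (SE 0.27), with RNA at 251 ± 23.8 and 256 ± 11.9 CPM (SD, n = 3) and footprints going from 101 ± 1.66 to 12.9 ± 2.55. Rock2 (ENSMUSG00000020580, chromosome 12 from 16894978 to 16988274) fell by 2.92 (SE 0.30), its RNA rising from 42.4 ± 2.85 to 87.9 ± 16.0 and its footprints falling from 157 ± 8.62 to 39.9 ± 11.4.

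Of 7931 genes, 1141 changed in TE, 504 higher and 637 lower, with 260 and 384 at least 2-fold. Among genes with higher TE, 159 were called higher in footprints alone, 156 lower in RNA alone and 85 higher in both assays. Among those with lower TE, 214 were called lower in footprints alone and 215 higher in RNA alone. In the integrated stress response list 5 of 13 rose and 0 fell (6 adjusted over the list alone; median 0.73; camera adjusted p = 8.5e-04). Ddit3 passed at 1.54 (SE 0.53, edgeR adjusted p = 0.042), but the call ended when any library other than RNA control 3 was left out, with values of 1.18 (without RNA control 1, adjusted p = 0.28) to 1.74 (without RPF control 1, adjusted p = 0.053). Ppp1r15a passed at 1.27 (SE 0.34), and the call ended without RNA control 3 (0.97, adjusted p = 0.080) or RPF control 1 (0.96, adjusted p = 0.076). Cebpb (0.76, edgeR adjusted p = 0.030) and Eif4ebp1 (0.73, edgeR adjusted p = 0.030) also passed. Their calls ended in 8 and 7 of the fits without 1 library. Trib3 (−0.10, adjusted p = 0.93), Atf5 (0.08, adjusted p = 0.90), Sesn2 (0.16) and Asns (−0.28, adjusted p = 0.18) did not pass. Slc7a11 was 5.46-fold lower in TE (interval 1.02 to 56.3) and did not pass either. Of mRNAs with regulatory upstream reading frames 4 of 11 rose and 2 fell (camera adjusted p = 0.18), Ppp1r15b falling by 0.87. The 4 that rose were Atf4, Ddit3, Ppp1r15a and Cebpb, which are also in the stress response list. Eprs fell by 0.58 (SE 0.17, edgeR adjusted p = 0.013), and the call ended without RNA control 1 (−0.51, adjusted p = 0.054).

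Ribosomal protein TE rose for 29 of 73 genes and fell for 2 (30 and 3 adjusted over the list alone; median 0.48; camera adjusted p = 7.6e-09), and 26 to 29 rose across the scalings. The camera adjusted p was only 0.016 with an estimated correlation. Rplp1 (2.46, edgeR adjusted p = 5.5e-09), Rpl39 (1.99) and Rps13 (1.94) are examples. Their control footprint counts were 187, 306 and 330 over the group, and near-identical copies leave the counts of ribosomal protein genes uncertain. Other TOP mRNAs had 5 of 18 higher and 2 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.21). Eef1a1 passed at 0.32 (adjusted p = 0.014), and the call ended without RNA control 1 (0.25, adjusted p = 0.084), RNA HF 3 (0.27, adjusted p = 0.066), RPF control 3 (0.29, adjusted p = 0.051) or RPF HF 2 (0.28, adjusted p = 0.051), while Eef2 was at 0.19 (adjusted p = 0.11). Nuclear-encoded respiratory chain subunits rose in 6 of 34 cases with 0 lower (camera adjusted p = 0.014; adjusted p = 0.10 with an estimated correlation), with Sdhb at 1.64, Ndufb5 at 1.47 and Ndufb8 at 1.38. Mitochondrially encoded mRNAs rose in 3 of 7 cases (camera adjusted p = 0.12), mt-Co1 by 0.76, and were called without RNA HF 3 (adjusted p = 0.031). They held only 0.0349% of footprint counts in control and 0.0315% in HF libraries. In footprints 0 of 7 rose and in RNA 7 of 11 fell, so this TE rise goes with the RNA fall. Mitochondrial ribosomal proteins had 3 of 32 higher and 1 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.098), Mrpl12 at 2.28, and were called without RPF HF 1 (adjusted p = 0.046). Ribosome biogenesis factors had 2 of 24 higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.32).

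Immediate early genes had 3 of 17 higher in TE and 0 lower (camera adjusted p = 0.039; adjusted p = 0.54 with an estimated correlation). That call also ended without RNA control 2 (adjusted p = 0.088), RNA control 3 (adjusted p = 0.087), RPF control 1 (adjusted p = 0.12) or RPF HF 3 (adjusted p = 0.092). Histones had 6 of 59 higher and 2 lower (median −0.10, though the test points up; camera adjusted p = 0.94). DNA replication genes had 0 of 26 higher and 5 lower (camera adjusted p = 0.62), with Pola1 at −1.04, Lig1 at −0.93 and Mcm4 at −0.65, and mitosis genes 3 of 24 higher and 1 lower (adjusted p = 0.75), the spindle motor Kif11 at −1.41. Collagens had 2 of 14 higher, Col1a1 at 0.36 (SE 0.10, edgeR adjusted p = 0.0067), and 4 lower, Col1a2 at −0.53 (camera adjusted p = 0.71). Other matrix genes had 2 of 19 higher and 2 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.71), Tnc at 0.62 and Fn1 at −0.86 (SE 0.08). In cytosolic tRNA synthetases 1 of 20 rose, Yars (0.65), and 2 fell, Eprs and Lars (−0.71), with a median of 0.01 that changes sign with the scaling (camera adjusted p = 0.93).

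Few members of the remaining lists changed in TE, and these lists were not called. Mitochondrial tRNA synthetases had 0 of 16 higher and 0 lower (camera adjusted p = 0.96), Iars2 at −0.44. Amino acid transporters had 1 of 14 higher, Slc7a5 at 0.81, and 0 lower (camera adjusted p = 0.92). Amino acid synthesis enzymes had 0 of 21 higher and 0 lower (camera adjusted p = 0.82), Psat1 at −0.08. TGF-beta targets had 1 of 14 higher and 1 lower (camera adjusted p = 0.54) and heat shock genes 2 of 12 higher and 0 lower (3 and 1 adjusted over the list alone; adjusted p = 0.71). Targets of p53 had 1 of 12 higher, the apoptosis effector Bax at 1.16, and 0 lower (camera adjusted p = 0.63). Unfolded protein response targets had 3 of 18 higher and 2 lower (adjusted p = 0.71) and sterol and fatty acid synthesis 1 of 23 higher and 2 lower (adjusted p = 0.82), with medians of 0.05 and 0.03 that change sign with the scaling. Median and test differed in sign for sterol synthesis and for NRF2 targets (0 of 10 higher, 0 lower; median 0.08; adjusted p = 0.96), autophagy (3 of 25 higher, 1 lower; median −0.01; adjusted p = 0.82), glycolysis and hypoxia (3 of 16 higher, 0 lower, 4 and 0 adjusted over the list alone; median −0.09; adjusted p = 0.71) and eIF2 and mTORC1 signalling (1 of 25 higher, 3 lower; median 0.11; adjusted p = 0.75). Single genes such as Sqstm1 (0.72, edgeR adjusted p = 9.0e-05) and Vegfa (1.22, adjusted p = 0.0015) rose. In the inflammatory list 0 of 4 tested genes passed. In these lists with 0 edgeR calls, 1 mitochondrial synthetase, 4 amino acid synthesis genes, 1 NRF2 target and 1 inflammatory gene had an unadjusted p under 0.05, and DESeq2 and limma voom called 0 in each.

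Among the genes with higher TE were Rflnb (3.53, SE 0.65), Zbtb45 (2.93, SE 0.80), Ldlrad3 (2.76), the ferritin light chain Ftl1 (2.66; near-identical pseudogene copies leave its RNA and footprint counts uncertain), Taf1d (2.54), an RNA polymerase I factor, and the small GTPase Rhog (2.49). Pink1, a mitochondrial kinase, passed at 2.65 (adjusted p = 0.022), and the call ended without RNA control 1, RNA HF 2, RPF control 3 or RPF HF 2, with values of 2.31 (adjusted p = 0.053, without RPF control 3) to 2.49 (adjusted p = 0.057, without RNA HF 2). Arrdc4 was 8.62-fold higher (interval 1.44 to 90.1), a call that ended without any library other than RNA control 2 and RPF control 1, with an adjusted p of up to 0.18 without RNA control 1. Its 2 control footprint counts were all in RPF control 1, and without that library the fitted log2 change went from 2.79 to 4.78, a value against 0 control counts that is no bound. Among those with lower TE were the retinoblastoma gene Rb1 (−3.62, SE 0.77), Mfhas1 (−3.11, SE 0.62, and −4.77 without RPF HF 2) and the DNA ligase gene Lig4 (−2.82, SE 0.75, and −4.52 without RNA control 3). Rb1 and Lig4 had few RNA counts in control cells, 13 and 10 over the group, against 92 and 80 in HF cells. Their unscaled footprint counts went from 95 to 22 and from 131 to 57, so the falls rest partly on RNA. At the higher end, unscaled RNA counts went from 126 to 38 for Rflnb and from 57 to 11 for Zbtb45. Footprint counts of Rflnb and Zbtb45 went from 31 to 46 and from 62 to 40, so their rises rest at least partly on RNA too. Adgra3 was 7.21-fold lower (interval 2.14 to 35.0) and Pmaip1 at least 2.18-fold lower, a call that ended without RNA control 1 (adjusted p = 0.056) or RPF control 1 (adjusted p = 0.071). Adcy7 was 7.91-fold lower (2.16 to 43.0), and its call ended without RNA HF 2 (adjusted p = 0.063) or RPF HF 1 (adjusted p = 0.10). TE is relative to the bulk of mRNAs within each assay, and footprints on upstream reading frames may be counted in the genes' totals.

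**Figure D3:**
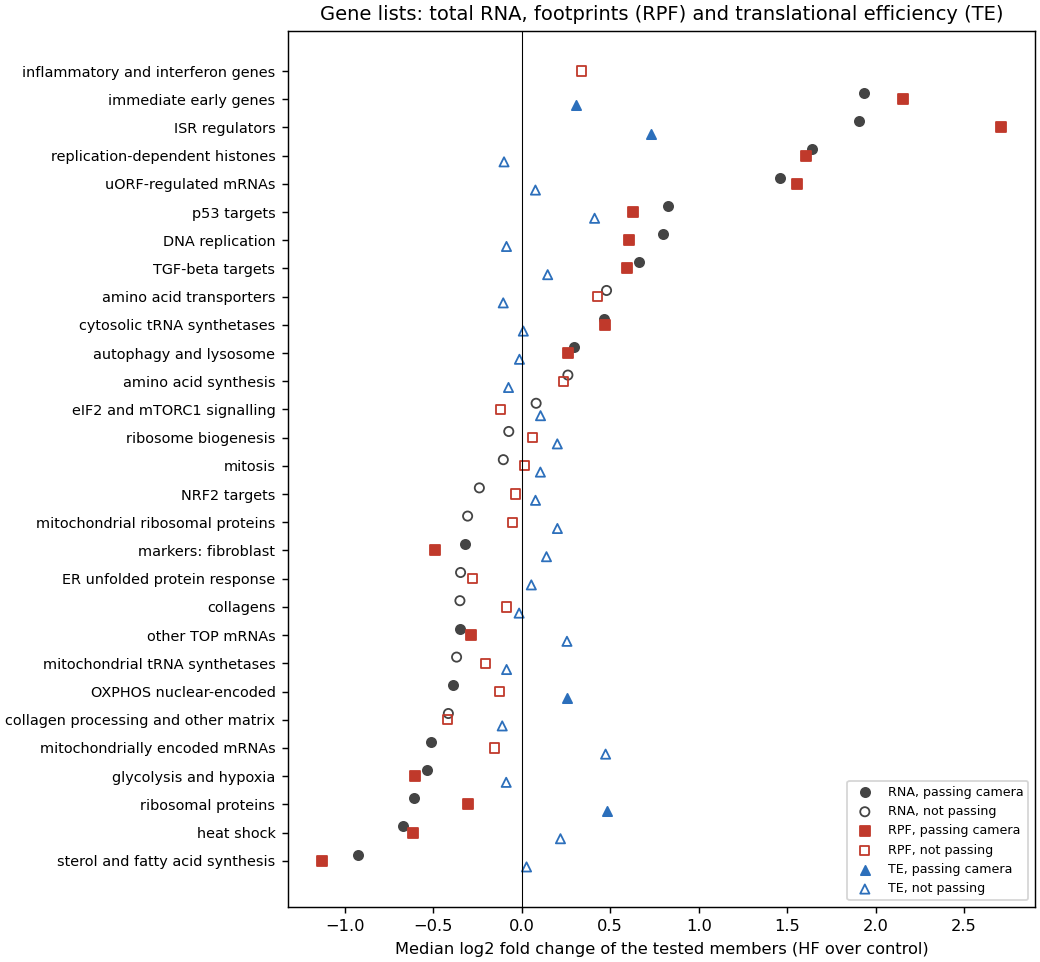
Median log2 fold change (HF over control) of each gene list in RNA, footprints and TE, filled where the camera adjusted p is under 0.05. Ribosomal proteins lie at −0.61 in RNA, −0.31 in footprints and 0.48 in TE, and histones at 1.64, 1.61 and −0.10.

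Of 53 markers of other cell types, few were measurable. In RNA 2 were tested, of which the epithelial keratin Krt19 rose by 1.28 and the neural tubulin Tubb3 did not pass (−0.81, adjusted p = 0.10), but passed without RNA control 3 (−1.10, adjusted p = 0.031) or RNA HF 1 (−1.33, adjusted p = 0.023). In footprints 3 were tested, with the monocyte receptor Cd14 falling by 1.93 and Krt19 at 0.27 not passing, though it passed without RPF HF 2 (0.45, adjusted p = 0.0079). Tubb3 footprints fell by 0.74, a call that ended without RPF control 2 (−0.60, adjusted p = 0.11) or RPF HF 2 (−0.53, adjusted p = 0.091). In TE 2 were tested and Krt19 fell by 0.99. Of endothelial, muscle and adipocyte markers 0 passed the filter. Fibroblast markers had 2 of 9 higher and 2 lower in TE (camera adjusted p = 0.93; median 0.14, though the test points down).

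**Figure D4:**
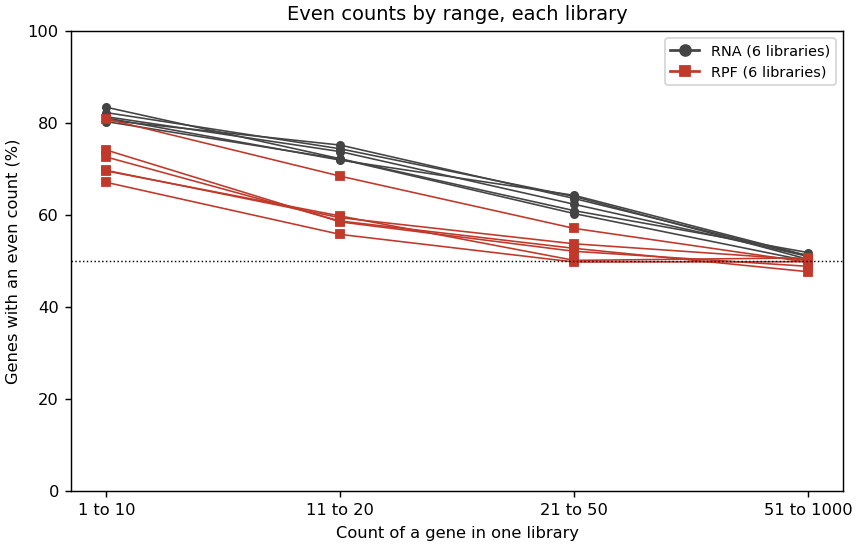
Share of genes with an even count, in percent, by range of counts, with a line for each of the 12 libraries. Among counts of 1 to 10 the share is 80.3% to 83.4% in RNA and 67.1% to 80.9% in footprint libraries, and among counts of 51 to 1000 it is 50.0% to 51.8% and 47.7% to 50.7%.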

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

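No test of a cause was run for the values given here, and Gas5 and Snhg1 were chosen after their values were seen. Long non-coding RNAs, which are not part of the footprint comparison, took 0.443% ± 0.0309 (SD, n = 3) of the footprint counts of HF cells against 0.200% ± 0.00333 in control cells. A signal in genes left out of the footprint comparison, above its level in control libraries, is what set this and the next values apart. Footprint counts of Gas5, a host gene of small nucleolar RNAs (snoRNA), went from 384 to 1256 (log2 fold change 2.29, SE 0.17, edgeR adjusted p = 1.5e-10 in the fit over all genes), while its RNA was at 0.16 (adjusted p = 0.38). Snhg1, another snoRNA host gene, was at 2.70 in footprints (SE 0.14, edgeR adjusted p = 1.9e-13) and 2.18 in RNA.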

How the results depend on the processing

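Chosen after seeing the data were thinning to the smallest library, halved counts and leaving out both doubted footprint libraries; the other alternatives were planned. Calls of changed genes stayed within 1.5 times of the reported number except where a 2-fold change was asked for, which by construction left 1969 in RNA, 1854 in footprints and 644 in TE. DESeq2 gave 3426, 3136 and 1065, voom 4078, 3932 and 1172, and a minimum count of 50 gave 2898, 2700 and 953. Thinning gave 3248, 2873 and 842. Leaving out both doubted footprint libraries, RPF control 1 and RPF HF 3, gave 2936 in footprints and 854 in TE. Leaving out 1 library gave 3361 to 3820 in RNA, 2899 to 3590 in footprints and 883 to 1073 in TE. Upper-quartile factors turned the balance of calls, to 1881 higher and 2151 lower in RNA and 1657 higher and 2043 lower in footprints. A minimum count of 50 gave 1432 higher and 1466 lower in RNA and 480 higher and 473 lower in TE, where 504 and 637 were reported, and halved counts gave 1931 and 1943 in RNA. TMM factors over all 12 libraries gave 1155 TE calls, 35.0% of them higher against 44.2%.

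Lists called with an estimated correlation numbered 11 in RNA, 4 in footprints and 2 in TE, against 17, 15 and 4. Some lost lists had an estimate below the preset 0.01, such as heat shock in RNA (−0.075) and fibroblast markers in footprints (−0.100). A stronger correlation between genes does not account for those losses, as that setting also uses only the residual degrees of freedom. Other estimates lay above 0.01, such as 0.32 for mitochondrially encoded mRNAs in RNA. The fry test called 25 in RNA, 23 in footprints and 7 in TE, since it does not compare a list with other genes. Without 1 library, 17 to 18, 15 to 17 and 3 to 5 lists were called. The correlation of RNA and footprint changes was 0.778 at a minimum count of 50, 0.751 over called genes, which by construction drops small changes, and 0.680 to 0.711 without 1 library, lowest without RPF HF 1. For the minimum count and RPF HF 1 the cause was not tested.

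Footprints of Lars2 reversed, from −1.53 to 0.57 (adjusted p = 0.53) with both doubted libraries left out; the cause was not tested. Of the genes named or eligible as list examples, a call was lost under some alternative for 10 of 133 in RNA, 11 of 134 in footprints and 41 of 114 in TE.

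With the replicate number as a block, 3933 genes were called in RNA, 3549 in footprints and 1075 in TE (1037 with the block by culture, which assumes that RNA and footprints share cultures). Correlations of same-numbered control and HF libraries were weak, 0.000319 to 0.0538 in RNA and 0.0123 to 0.142 in footprints. The same number was the best match in 4 of 6 cases, but some such matches come by chance. Same-numbered RNA and footprint libraries, which the block by culture pairs, correlated at 0.00205 to 0.0182 in control and −0.0242 to 0.0134 in HF cells. There the same number was the best match only for replicate 3. Whether the numbers pair libraries stays open. The planned comparison of proline codons with TE was not run, as no coding sequences were analysed here.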

Other observations

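The tests on ribosomal protein depth and TOP mRNAs, on S phase, on halved counts and on other splits were chosen after the results were seen; those on near-identical copies were written down before. Non-coding RNAs also differed after HF. Of 67 long non-coding RNAs tested in RNA, 23 rose and 9 fell (median log2 fold change 0.18), and of 48 tested in footprints 22 rose and 4 fell (median 0.79). Of 9 tested host genes of snoRNAs, 5 were higher and 2 lower in RNA, and of 9 in footprints 6 were higher and 1 lower. Snhg17 was at 2.38 in RNA and 4.43 in footprints, Snhg12 at 1.48 and 3.27, and Snhg6 at 1.07 and 1.40, while Snhg3 fell by 1.41 and 1.04. The nuclear RNAs Neat1 (1.25 and 2.29) and Tug1 (1.41 and 1.34) rose. Of 253 pseudogenes tested in RNA 11 rose and 56 fell (median −0.42), and of 455 in footprints 58 rose and 85 fell (median −0.14). These groups were formed after the values were seen.

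The first pattern is the TE rise of ribosomal protein mRNAs. Were reads lost to near-identical copies mainly in poorly counted members, the rise would sit there. The 36 better-counted genes had a median of 0.513 against 0.357 for the other 37. The interval of 0.0627 to 0.700 for the former resamples genes, which are not independent. A gene's count does not measure its number of copies, and the treatment of reads that map to several places is unknown. The split therefore does not decide this explanation. Unequal depth is argued against by a camera adjusted p of 9.0e-08 with every library thinned to the smallest total. A change of TOP mRNAs as a class stays open, since the other TOP mRNAs were not called (camera adjusted p = 0.21), which does not show that they behave otherwise. An effect of HF on the translation of these mRNAs stays open too and was not tested apart from the fall of their RNA.

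The second pattern is the rise of replication-dependent histones. Reads moving between near-identical copies would leave the summed histone counts in place, but their share of protein-coding counts rose from 1.09% ± 0.0731 (SD, n = 3) to 3.14% ± 0.0983 in RNA and from 2.16% ± 0.0510 to 6.00% ± 0.283 in footprints, with the lowest HF share 2.58 times the highest control share in RNA and 2.61 times in footprints. A larger share of cells in S phase is consistent with the rise of DNA replication genes in RNA (adjusted p = 0.023 with an estimated correlation), and mitosis genes were not called. An effect of HF on histone mRNA itself stays open and was not tested.

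The third pattern is the even low counts in all 12 libraries. Were reads counted in pairs, calls might be inflated. Halved counts gave 3874 of 7663 tested genes in RNA, 3690 of 7125 in footprints and 1211 of 6517 in TE, against 3992 of 9145, 3625 of 8379 and 1141 of 7931. Since fewer genes were tested and the fit estimates the spread anew from the halved counts, this does not decide it. The reason for the even counts stays open, since the sources used here do not give it.

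For chance as the source of the calls, the 10 splits of 6 libraries are too few to give a share under 0.05. In RNA and in footprints 1 of 10 splits, the real one, gave as many genes (3992 and 3625), and the highest other gave 0 in each. For TE, 3 of 100 splits gave as many as the real 1141, and the highest other gave 1192. That share rests on the kinds of split drawn, so it does not exclude chance. Both other splits of that size were among 23 that parted 1 assay by treatment (median 70 genes), and 76 splits that parted neither gave at most 0.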
